A study of Drosophila melanogaster with 3 samples.

How the data were processed

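ChIP-seq libraries were made from whole embryos of transgenic flies that express CG34224 fused to eGFP, precipitated with an antibody against GFP. Chromatin was sheared by sonication to 200 to 800 bp, per the labels. All 3 libraries carry a biological replicate number in the labels and share 1 strain; the grouping rests on those labels. A control experiment named in the labels is not analysed here.

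The authors deposited 2 kinds of peak list for each replicate, ranked and thresholded by the irreproducible discovery rate (IDR), and 8 lists of the whole series, 4 ranked and 4 thresholded, of which 1 is named conservative. Per the deposited descriptions the coordinates are on assembly dm6, the series lists derive from the alignments of all 3 libraries together, and each thresholded list draws on 1 input file that the ranked lists do not. The aligner, the peak caller, the IDR version and the pair of replicates behind each series list are not given in the sources used here. The deposited score of a peak is its IDR-scaled value of at most 1000, and the lowest score in every thresholded list was 830. The deposited signal of a peak is the authors' peak caller's value on a scale the descriptions do not state; it was used only to rank and describe peaks within a list. No read counts accompany the peaks, so depth per sample is unknown and list length stands in its place, with 2667, 2844 and 4146 thresholded peaks in replicates 1, 2 and 3. The remaining thresholded series lists are named a, b and c by length, with 4958, 4278 and 3730 peaks.

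Peaks on chromosomes 2L, 2R, 3L, 3R, 4, X and Y were used, and every peak end lay within the reference chromosome lengths of Release 6. Start sites came from the Ensembl annotation BDGP6.54, release 115, without transposable elements; microRNA genes were told from other non-coding genes with the RefSeq gene table. Peaks of different lists counted as shared when they overlapped by at least 50% of the shorter peak. Intervals listed more than once with different summits were 1 peak in overlap counts. A promoter peak had its summit within 500 bp of a start site. Random placements, 1000 per test, kept each peak's width and arm.

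Gene lists, 30 in all, and consensus sequences, 28 in all, were fixed before the data were examined, as were the comparisons, tests and alternatives except where stated. A gene was bound when a conservative summit lay within 500 bp of one of its start sites. Protein-coding lists were compared with all other protein-coding genes and non-coding classes with all other genes, by Fisher's exact test, 2-sided, with Benjamini-Hochberg adjustment over the 30 lists. The symbols h and nos matched no gene of the annotation and were left out. Sequence windows of 101 bp at conservative summits were compared with windows centred 500 bp to either side, on both strands, by Fisher's exact test with Benjamini-Hochberg adjustment over the 28 consensus sequences or the 2080 6-mers. Genes and windows are not biological replicates, and Wilson intervals on shares of genes or peaks cover counting error only, not the spread between replicates. Differences of medians were tested with 100000 permutations, 2-sided. The X chromosome was tested with exact binomial tests against the share of start sites.

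The rule for the items named was fixed as well: the 20 conservative peaks of highest signal found in all 3 replicates, named by the nearest protein-coding start site; up to 4 of the strongest bound members of each gene list; CG34224 with peaks within 5 kb; the 10 enriched 6-mers of smallest p; and each consensus past the threshold with the first 5 of the others.

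The overlap, gene list, sequence and median steps were first run on simulated data, the X chromosome test was not. In the overlap step, 1500 peaks were planted in each of 3 lists of 3000 and 1500 were found as shared. In the gene list step on 13968 genes, 19 of 20 lists with a planted bound share were called and 1 of 180 unchanged lists. The simulated lists were random genes, equal in size and longer than most of the lists that later did not pass. Their rate of calls therefore does not apply to lists of 8 to 15 genes or to lists of neighbouring genes. In the 6-mer step, 2 of 2 6-mers of a planted DRE were called with 10 others, and 0 of 2080 without planting. In the consensus step the planted DRE was called and 0 of 28 without planting. Both sets of windows in these sequence steps were drawn at random from the genome. The rates of calls therefore do not apply where summits and flanks differ in base composition. The permutation of medians called 5 of 100 runs without a difference and 87 of 100 with one.

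Alternatives changed the overlap rule (any overlap, or summits within 100 bp), the promoter distance (250 or 1000 bp), the peaks (the upper 50% by signal, the 1000 strongest), the list (each other series list and each replicate), the windows (51 or 201 bp), the control windows (start sites with no peak within 1 kb) and left out each replicate in turn. Alternatives chosen after seeing the data left out peaks that overlap a stronger peak of the same list, and shifted the bound calls along the gene order 10000 times. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.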

Results

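Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate the protein CG34224, fused to the green fluorescent protein variant eGFP, on the genome of Drosophila melanogaster embryos. Whole embryos 0 to 24 hours old were used, so each library mixes all embryonic tissues and stages. All 3 libraries belong to a single group and are biological replicates 1, 2 and 3 per the labels. The comparisons open to this design are how far the replicates share their bound sites, where in the genome and at which genes those sites lie, and which sequences they hold. The peak lists carry no read counts, so sequencing depth is unknown, and the length of a list is the only depth-related value given here: 2667 peaks in replicate 1, 2844 in replicate 2 and 4146 in replicate 3. The authors' conservative list, derived from the 3 libraries together, held 4395 peaks with a median width of 536 bp. Of its 4360 distinct peaks, 2044 (46.9%) were found in all 3 replicate lists and 607 (13.9%) in none of them. The gene list and sequence results rest on the conservative list.

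The strongest binding sites were promoters, and the first 4 ranked between 1 and 5 in every replicate. The peak with the highest signal lay 56 bp upstream of the start site of mtSSB (FBgn0010438), the single-stranded DNA-binding protein of mitochondria, at chromosome 3R 16205084 to 16205543 (dm6), with a signal of 2322 in the conservative list; it ranked 1, 1 and 2 in replicates 1, 2 and 3. Creld (FBgn0031217) followed at 2L 102156 to 102602 with a signal of 2133 and ranks 2, 2 and 1. Next came the promoter between Ube3a (FBgn0061469), a ubiquitin ligase gene, and CG7600 at 3L 11210340 to 11210896 with a signal of 1864, and the promoter of Rpn6 (FBgn0028689), a subunit of the proteasome lid, and ave at 2R 14752153 to 14752640 with a signal of 1776. The other named peaks belonged to RhoGAP93B, Hsepi, Pym, CG14441, CG8613, Nrg, Sry-alpha, hts, Prosalpha7, SMC1, RpL32, Fit2, CG4502, CG11857, Capr and Jwa, with signals from 1663 down to 1310.

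All 20 of these peaks had their summit within 167 bp upstream of a protein-coding start site, and 7 had the start site of a further protein-coding gene within 500 bp. At Rpn6 and Pym the summit fell in an annotated intron, at Capr in a 5' UTR, and at the remaining genes outside annotated genes. None ranked below 41 in any replicate list. At the CG34224 gene itself (FBgn0085253, 2R 11237172 to 11237644, minus strand) the conservative list held no peak within 5 kb. The list of replicate 1 held 1 peak in that window with a signal of 65.1, those of replicates 2 and 3 held 0, and the shortest series list held 2, the higher with a signal of 106. The ranked lists held 6, 12 and 11 peaks within this window of 5 kb in replicates 1, 2 and 3, with highest scores of 1000, 821 and 829 beside the lowest listed score of 830. Over the gene body itself they held 0 peaks in replicates 1 and 2, and 2 in replicate 3 with a highest score of 275.

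Replicates shared most of their peaks when the shorter list was taken as the base. Of the peaks of replicate 1, 77.1% were found in replicate 2 and 87.7% in replicate 3, and of those of replicate 2, 73.8% were found in replicate 1 and 87.8% in replicate 3. Replicate 3, the longest list, shared 57.4% with replicate 1 and 59.6% with replicate 2. Merging the lists gave 4358 regions, of which 1885 (43.3%) were held by all 3 replicates. In 1000 random placements of the peaks on their own chromosome arms the share in all 3 never exceeded 0.0317%, a one-sided permutation p of 0.001, the smallest these placements can give. Placements spread peaks evenly over the arms, while most listed peaks lay at promoters. This p therefore does not test whether replicates share the same promoters beyond a common location at promoters. Replicate 3 alone held 1311 of its peaks in no other list (31.7%), against 236 in replicate 1 (8.85%) and 256 in replicate 2 (9.03%). The lists differ in length, which limits the share of a longer list that a shorter one can hold.

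**Figure D1:**
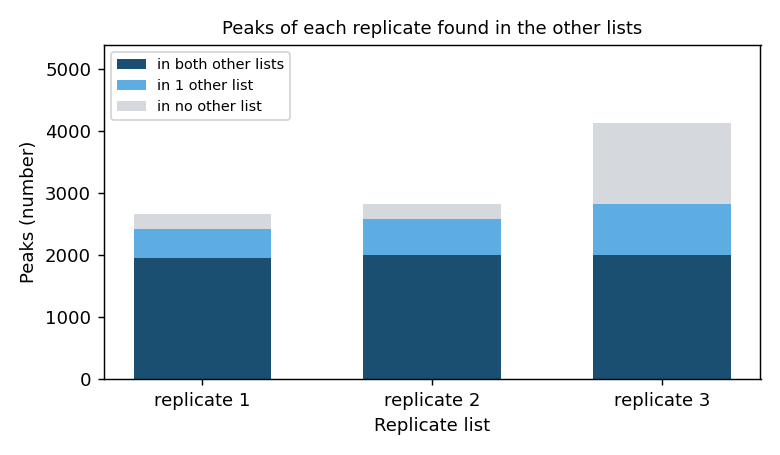
Number of peaks on the main chromosome arms in each replicate list (vertical axis), divided by whether they overlapped a peak of both other lists, of 1 other list or of none. The number found in both others was 1962, 2002 and 2013, while those found in no other list numbered 236, 256 and 1311 in replicates 1, 2 and 3.

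Peaks found in all 3 replicates were the stronger ones of each list. Their median signal percentile was 62.5 in replicate 1, 63.8 in replicate 2 and 74.98 in replicate 3, against 14.1, 17.7 and 24.6 for peaks found in that replicate alone. The difference was 48.3 ± 2.13 percentile points (SD, n = 3 replicates), and the 2-sided permutation p was 1e-05 in each list, the smallest that 100000 resamples can give. Percentiles were taken within a list, since the authors' signal is not comparable between lists.

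CG34224-eGFP peaks lay at promoters. The share of summits within 500 bp of an annotated start site was 89.4% ± 2.92 (SD, n = 3), with 90.9% in replicate 1, 91.3% in replicate 2 and 86.1% in replicate 3, against 13.6% ± 0.0466 in random placements (one-sided permutation p = 0.001 in each list, the smallest possible). Introns outside this distance took 6.04% ± 1.72 of the summits and intergenic sequence 3.17% ± 0.754. Coding exons (0.339% ± 0.152), 5' UTRs (0.315% ± 0.112), 3' UTRs (0.490% ± 0.114) and exons of non-coding genes (0.221% ± 0.102) together held few (SD, n = 3 for each). In the conservative list 3779 of 4393 peaks on the main arms were promoter peaks (86.0%, 95% Wilson interval 85.0 to 87.0).

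Summits sat just upstream of the start site. Among peaks within 500 bp of a protein-coding start site the median summit position was -33.3 ± 3.06 bp (SD, n = 3), 69.4% ± 3.23 of the summits were upstream, and 85.7% ± 2.06 lay within 150 bp on either side. A peak was found at 2941, 3111 and 4000 protein-coding genes in replicates 1, 2 and 3, or 24.0% ± 4.07 of 13968 annotated genes (SD, n = 3), and at 4153 (29.7%) in the conservative list.

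**Figure D2:**
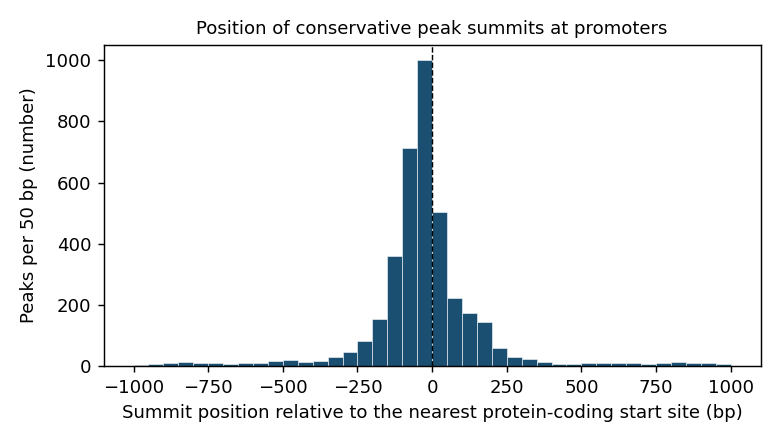
Number of conservative peaks per 50 bp (vertical axis) by the position of the summit relative to the nearest protein-coding start site in bp, negative values being upstream. The median position among those within 500 bp was -32 bp, and 67.3% were upstream.

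Promoter peaks were stronger than distal ones. The ratio of their median signals was 1.36 ± 0.0448 (SD, n = 3). In replicate 1 the medians were 93.5 for 2424 promoter peaks and 68.5 for 243 distal peaks. They were 88.7 and 63.0 in replicate 2, and 124 and 93.9 in replicate 3. The 2-sided permutation p was 1e-05 in each replicate, the smallest the resampling allows.

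The X chromosome held peaks at a density close to that of the autosomes. The density of peaks per Mb on X was 0.969 ± 0.0511 times that on arms 2L, 2R, 3L and 3R (SD, n = 3), beside a ratio of 0.928 for start sites. X held 17.0%, 18.2% and 16.8% of the peaks in replicates 1, 2 and 3, against 16.7% of the start sites. Exact binomial tests, 2-sided and adjusted over the 3 replicates, gave p = 0.884, 0.116 and 0.884, so no departure from the share of start sites was detected. The conservative list held 22 peaks on chromosome 4 and 0 on the Y chromosome.

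Genes for protein synthesis and turnover were bound more often than other protein-coding genes. Among 73 mitochondrial ribosomal protein genes 45 had a promoter peak in the conservative list (61.6%, against 29.6% of other protein-coding genes, adjusted exact p = 7.79e-08), led by mRpL4 with a signal of 1135, mRpL42 with 860 and mRpL10 with 725. Of 86 cytoplasmic ribosomal protein genes 47 were bound (54.7%, adjusted exact p = 5.17e-06), with RpL32 at 1366, RpS2 at 1169 and RpS28a at 836. Proteasome genes were bound in 26 of 48 cases (54.2%, adjusted exact p = 0.00123), among them Rpn6, Prosalpha7 (signal 1417) and Rpn10 (885). Translation initiation and elongation factor genes were bound in 24 of 51 cases (47.1%, adjusted exact p = 0.0221), including eIF3f1 with a signal of 1071 and eIF2gamma with 777. That last call was lost with start sites within 250 bp (adjusted exact p = 0.0555; 0.00147 to 0.0555 over its alternatives). Over the replicate lists the bound shares were 46.6% ± 8.55, 42.6% ± 6.404, 45.8% ± 7.51 and 43.1% ± 5.88 in the same order (SD, n = 3).

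The highest bound share was that of insulator and architectural protein genes, whose products organise chromatin domains. A promoter peak was present at 13 of 15 (86.7%, Wilson interval 62.1 to 96.3, adjusted exact p = 2.57e-05), and the share over replicates was 73.3% ± 6.67 (SD, n = 3). Its strongest members were pita (signal 619), BEAF-32 (478), mod(mdg4) (467) and Ibf1 (442). Ibf2 had the same strongest signal as Ibf1, so 1 peak may count for both. Cyclic shifts that keep neighbouring genes together, chosen after the data were seen, gave an adjusted permutation p of 0.000857. Dref, the gene of the factor that binds the DNA replication-related element (DRE), had a peak with a signal of 438 found in all 3 replicates. The members without a peak were M1BP and su(Hw). These members, Dref and Ibf2 are named after their values were seen.

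Some patterning and chromatin lists also passed as higher in the conservative list, while in the replicate lists they were above other genes but did not all pass. Segment polarity genes were bound in 8 of 11 cases (72.7%, adjusted exact p = 0.0110), led by pan (signal 667), fz (427), smo (413) and ptc (218). Polycomb and trithorax group genes were bound in 10 of 16 cases (62.5%, adjusted exact p = 0.0234), led by Scm (610), Pc (400), Su(z)12 (337) and Psc (284). Ecdysone response genes were bound in 7 of 11 cases (63.6%, adjusted exact p = 0.0440), led by usp (561), ftz-f1 (387), Hr3 (318) and Eip75B (249). Over the replicate lists the bound shares were 48.5% ± 13.9 for segment polarity, 33.3% ± 14.4 for Polycomb and trithorax and 39.4% ± 13.9 for ecdysone response genes (SD, n = 3), against 21.0% to 28.6% of other protein-coding genes. The segment polarity call was absent in 6 of 11 alternatives (adjusted exact or permutation p from 0.00529 to 0.676), replicates 1 and 2 among them (0.131 and 0.495). The Polycomb and trithorax call was absent in 4 (0.0140 to 0.958), among them replicates 1, 2 and 3 (exact p of 0.875, 0.958 and 0.161). The ecdysone call was absent in 8 (0.0283 to 0.936), among them replicates 1, 2 and 3 (exact p of 0.458, 0.936 and 0.161) and cyclic shifts that keep neighbouring genes together, chosen after the data were seen (adjusted permutation p = 0.0947).

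Sensory receptor, cuticle and histone genes had no promoter peak. A promoter peak was present at 0 of 119 odorant and gustatory receptor genes (Wilson interval 0 to 3.13%, adjusted exact p = 1.95e-17) and at 0 of 70 cuticle protein genes (0 to 5.20%, adjusted exact p = 1.90e-10). The 3 replicate lists held 0 promoter peaks at them as well. Replication-dependent histone genes had 0 of 111 (adjusted exact p = 2.13e-16). The histone genes are near-identical repeated copies in which reads are hard to place, so their value is uncertain.

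Among genes of small RNAs, tRNA genes were bound above all other genes and snoRNA and microRNA genes below. A peak lay within 500 bp of 127 of 290 tRNA genes (43.8%, against 24.4% of all other genes, adjusted exact p = 8.02e-12). The exact test treats genes as independent, while 1 peak can count for several neighbouring genes. Cyclic shifts that keep neighbouring genes together, chosen after the data were seen, gave an adjusted permutation p of 0.000857. The strongest signals were at tRNA:Gly-TCC-1-2 with 780, tRNA:Gly-GCC-1-9 and tRNA:Trp-CCA-2-2, both 555, and tRNA:Leu-AAG-1-3 with 479. The equal signals of 555 may be 1 shared peak. The number of bound tRNA genes was 69 in replicate 1, 80 in replicate 2 and 145 in replicate 3, or 33.8% ± 14.2 (SD, n = 3). The call was lost in the upper 50% of conservative peaks by signal (adjusted exact p = 0.0645; 8.36e-21 to 0.0645 over its alternatives). snoRNA genes were bound in 23 of 269 cases (8.55%, adjusted exact p = 5.94e-11), led by snoRNA:Me18S-A1576 at 1144, and microRNA genes in 15 of 260 (5.77%, adjusted exact p = 5.47e-15), led by mir-9370 at 579. Over the replicate lists these shares were 5.20% ± 0.984 and 3.59% ± 0.888 (SD, n = 3). For snoRNA and microRNA genes the annotated 5' end of the RNA served as the start site, and whether it is a promoter was not tested. Their low shares therefore need not mean that their promoters lack peaks. The strongest signal at mir-995 equalled that at Cdk2 (575), so 1 peak may count for both.

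The other 16 of the 30 lists did not pass the threshold. Most of them hold 8 to 15 genes, so a difference in them may go undetected. Their bound counts were 2 of 8 Hox genes (abd-A, signal 327, and Ubx, 302), 3 of 12 gap and maternal anterior-posterior genes (ems, btd and oc, btd with a peak in 0 replicate lists), 3 of 9 pair-rule genes (ftz-f1, opa and slp2, the last in 0 replicate lists) and 4 of 14 dorsal-ventral patterning genes (sog, dpp, brk and dl). Neurogenesis genes had 4 of 15 (esg, SoxN, elav and pros), mesoderm and muscle genes 4 of 14 (Mef2, tin, Tm1 and how), haemocyte genes 2 of 9 (ush and crq), gut and endoderm genes 2 of 9 (fkh and wg, the latter in 0 replicate lists), tracheal genes 3 of 8 (sima, tgo and bnl) and germ cell genes 3 of 8 (tud, pgc and gcl). Metabolic and stress lists had 28 of 80 respiratory chain and ATP synthase genes (ND-B14.5A, UQCR-14 and COX7A highest), 12 of 33 V-ATPase genes (Vha16-5 and VhaSFD highest), 8 of 20 heat shock genes (Hsp60A and Hsp83 highest) and 9 of 21 cell cycle and replication genes (CycB, Mcm5 and Cdk2 highest). Antimicrobial response genes had 1 of 14 (AttD) and the Enhancer of split complex 0 of 11. The smallest adjusted exact p among them was 0.0822, that of the Enhancer of split complex, which passed as lower in 2 of 11 alternatives (0.0443 to 0.512). Cell cycle and replication genes passed as higher in the list of replicate 2 alone (adjusted exact p = 0.0383; 0.0383 to 0.586 over alternatives).

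**Figure D3:**
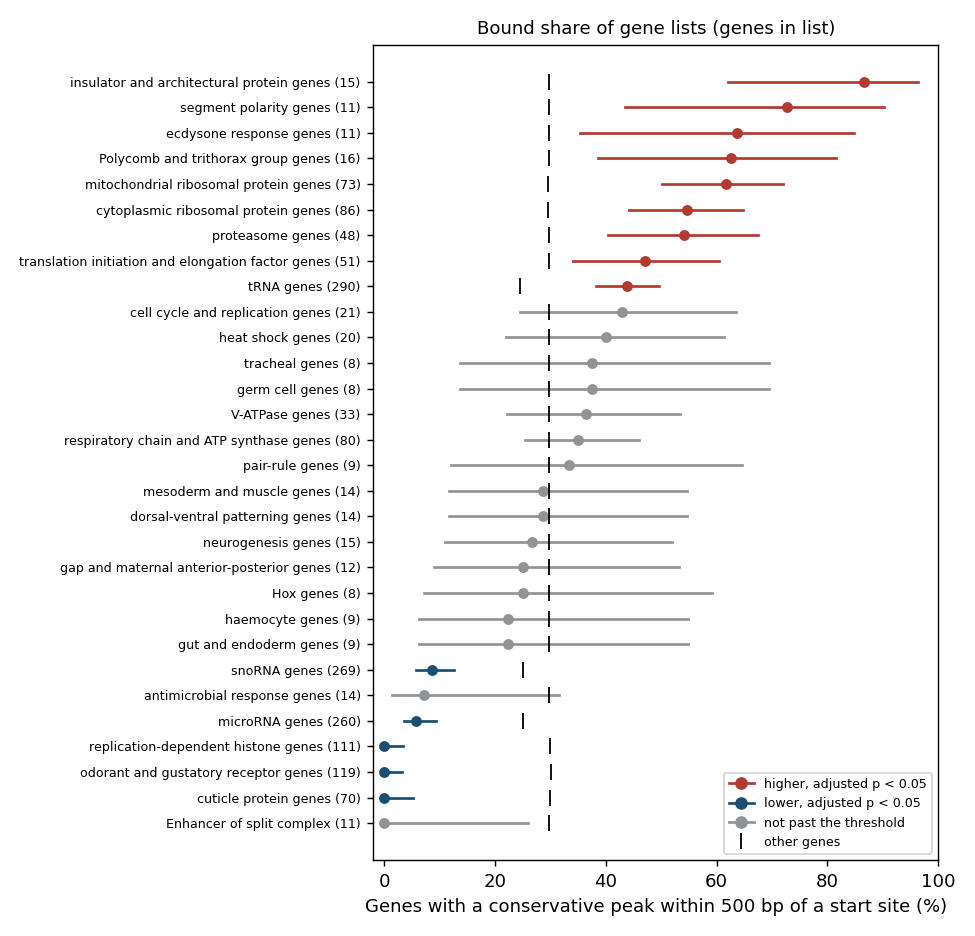
Percent of the genes of each list with a conservative peak within 500 bp of a start site (points, horizontal axis), with 95% Wilson intervals (lines) and the share among other genes (black ticks); the number of genes stands in parentheses. Red lists were higher and blue lists lower at an adjusted p under 0.05, from 86.7% for insulator and architectural protein genes to 0 for cuticle protein genes.

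The sequence TATCGATA, the DRE, marked the summits. It was present in 14.2% of the windows reaching 50 bp to either side of conservative summits and in 0.421% of windows centred 500 bp to either side, a 33.8-fold difference (Fisher's exact test, adjusted exact p = 3.70e-256). In the replicate lists the summit share was 17.5% ± 3.28 (SD, n = 3), and the ratio to the flanks ranged from 42.4 to 76.4. The nearest DRE lay a median of 41.5 bp from the summit among the 1160 peaks that had one within 500 bp. At promoter peaks the share was 15.7%, against 0.694% at start sites without a peak.

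Other sequences, core promoter elements among them, were enriched to a lesser degree. The Ohler E-box was present in 2.71% of summit windows (13.2-fold over the flanks, adjusted exact p = 6.36e-38), Motif 1, bound by M1BP, in 1.73% (10.1-fold, adjusted exact p = 2.98e-22), Motif 6 in 0.637% (7.0-fold, adjusted exact p = 2.29e-07) and Motif 7 in 6.37% (5.54-fold, adjusted exact p = 4.38e-58). GAGA repeats were found in 5.78% (3.603-fold, adjusted exact p = 2.88e-36) and ZIPIC sites in 3.48% (3.15-fold, adjusted exact p = 5.39e-19). Over the replicate lists the ratio to the flanks was 23.2 ± 13.5 for Motif 1 (17.4, 38.7 and 13.6 in replicates 1, 2 and 3) and 11.1 ± 1.67 for the Ohler E-box. By ratio Motif 1 stood above the Ohler E-box in each replicate and below it in the conservative list. Motif 1 was present in only 0.131%, 0.0528% and 0.121% of the flanks of replicates 1, 2 and 3, so its ratios rest on few windows. By summit share the Ohler E-box was the higher in each replicate (2.92%, 2.36% and 2.22%, against 2.29%, 2.04% and 1.64%). The ratio to the flanks was 9.81 ± 2.96 for Motif 6, 7.08 ± 0.754 for Motif 7, 3.36 ± 0.511 for GAGA repeats and 2.80 ± 0.185 for ZIPIC sites (SD, n = 3). The Myc E-box (1.67-fold, adjusted exact p = 0.00107) and E2F sites (1.56-fold, adjusted exact p = 0.0171) passed in the conservative list. The Myc E-box call was absent in 5 of 11 alternatives, replicates 1, 2 and 3 among them, and the E2F call in 7, replicates 1 and 3 among them (highest adjusted exact p = 0.510 and 0.273). Against start sites without a peak the enrichment was 5.93-fold for the Ohler E-box, 4.37-fold for Motif 7, 2.47-fold for Motif 1, 2.07-fold for ZIPIC sites and 2.02-fold for GAGA repeats. Motif 6 did not pass against start sites without a peak (0.688% against 0.440%, adjusted exact p = 0.0913; 1.93e-10 to 0.0913 over alternatives).

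Zelda sites (0.387% against 0.945%, adjusted exact p = 0.00107), the nuclear receptor site AGGTCA (1.46% against 2.72%, adjusted exact p = 8.81e-06) and the twist E-box (6.10% against 7.26%, adjusted exact p = 0.0304) were less frequent at summits than in the flanks. The Zelda difference was not past the threshold in 2 of 11 alternatives, and the twist E-box difference in 5. Start sites without a peak were an alternative that ended both (adjusted exact p = 0.104 and 0.850, with 0.000345 to 0.149 and 4.26e-05 to 0.850 over alternatives). TATA boxes (1.59% against 1.22% in the flanks, adjusted exact p = 0.171) and initiator elements (21.0% against 19.6%, adjusted exact p = 0.111) did not pass, and both were less frequent at promoter peaks than at start sites without a peak (1.75% against 3.59% and 20.7% against 28.8%, adjusted exact p = 2.95e-09 and 2.20e-24). In the opposite direction, TATA boxes passed as higher than the flanks in 3 of 11 alternatives and initiator elements in 2. Sites for su(Hw), CTCF and GATA factors did not pass (adjusted exact p = 0.783, 0.192 and 0.305), nor did the other 11 of the 28 consensus sequences. CTCF sites passed as higher in 3 of 11 alternatives and GATA sites as lower in 3, start sites without a peak among them (adjusted exact p = 0.000471; 0.000471 to 1 over alternatives). Against those start sites the heat shock element also passed as higher (2.78-fold, adjusted exact p = 0.0103) and Caudal sites as lower (0.327-fold, adjusted exact p = 0.000742), each in 1 of 11 alternatives. Pho sites passed as higher in 1 alternative, homeodomain sites as lower in 1 and SRF sites as lower in 2.

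**Figure D4:**
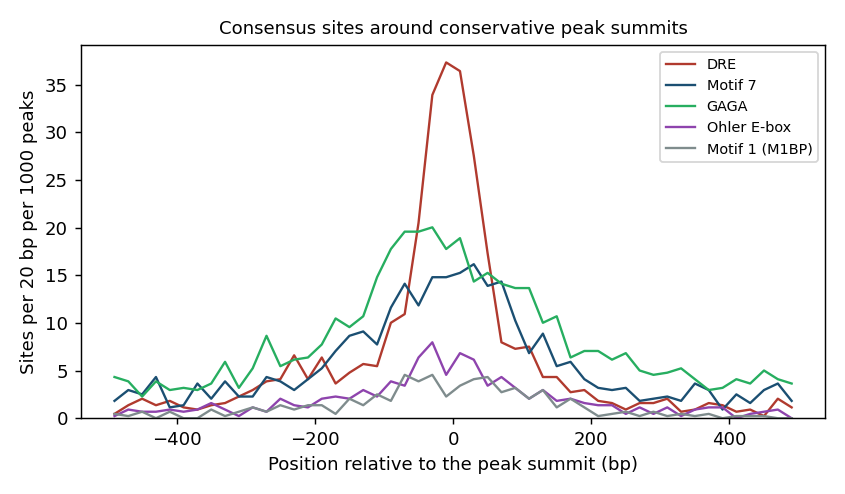
Number of consensus sites per 20 bp and per 1000 conservative peaks (vertical axis) by position relative to the summit in bp, for 5 of the enriched sequences. The DRE curve is highest next to the summit, with 37.3 sites per 1000 peaks in the 20 bp before it and 36.4 in the 20 bp after it.

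Of 2080 6-mers, 363 were enriched at summits and 566 were depleted. Of the 10 with the smallest p, all but ACTATC held CGATA or ATCGA on either strand, both part of the DRE. ACTATC shares only the shorter run TATC with it. TATCGA was present in 31.8% of summit windows and 3.64% of flanks, ATCGAT in 28.6% and 3.56%, and CGATAG in 24.5% and 2.28%; their p values were below the range of double precision, with log10 p of -426, -362 and -346. CGATAA (19.5% against 4.21%), ATATCG (17.4% against 3.95%), ACTATC (13.7% against 2.81%), CGATAC (11.0% against 2.32%), CCGATA (10.7% against 2.42%), AATCGA (17.9% against 6.85%) and GCGATA (11.7% against 3.46%) followed, each 2.61-fold or more above the flanks. Of the conservative peaks 11.5% overlapped a stronger peak of the list, so the tests count some sequence more than once; leaving these peaks out, an alternative chosen after the data were seen, gave 355 enriched 6-mers.

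**Figure D5:**
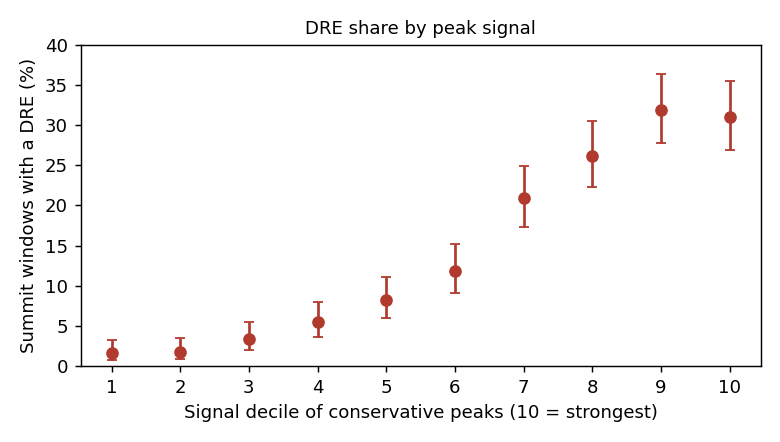
Percent of summit windows with a DRE (points, vertical axis) in each signal decile of the conservative list (horizontal axis, 10 being the strongest), with 95% Wilson intervals. The share was 1.59% in the weakest decile, 31.9% in decile 9 and 31.0% in the strongest.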

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

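The tests here of ribosomal protein genes, of tRNA genes far from protein-coding genes and of sequences at tRNA peaks were chosen only after the results were seen, while the comparison with start sites without a peak was planned and its use as a test of an explanation was set after its value was seen. The design has 1 group, so no biological explanation of the patterns in this part was tested.

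A signal outside the comparisons of the report appeared on the mitochondrial genome. The list of replicate 2 held 3 summits there in 1 interval, 1309 to 3131, with signals of 8326, 4950 and 4906, against at most 707 on its main arms; replicates 1 and 3 held 0, ranked lists included.

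Peaks that reached the lowest listed score of 830 in a ranked list were absent from the thresholded list of the same replicate in 106 cases in replicate 1, 93 in replicate 2 and 151 in replicate 3. Of their 156 merged regions 67 were left out in all 3 replicates, and their promoter shares were 69.2%, 72.5% and 65.5%. The rule that removed them is not given in the sources used here.

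The DRE was 22.6 times as frequent at promoter peaks as at start sites without a peak, which argues against a property of all start sites. The median ratio of the 591 other 8-mers of the same base composition was 0.915 and their highest was 13.9, which argues against composition. Unspecific recovery of highly transcribed promoters stays open, since transcription was not measured here and 54.7% of cytoplasmic ribosomal protein genes were bound (Wilson interval 44.2 to 64.7), above the 29.6% of other protein-coding genes. Whether CG34224 contacts the DRE itself or is brought there by another factor stays open and was not tested.

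Of 81 peaks near a tRNA start site and no protein-coding one, 0 held a DRE (Wilson interval 0 to 4.53) and 6.17% held CGATA, against 11.4% and 39.4% of peaks near protein-coding start sites alone at the same signal deciles (2-sided permutation p = 0.00012 and 2e-05, the latter the smallest possible); peaks near no start site held a DRE in 5.05% of cases. Of the 167 tRNA genes over 2 kb from protein-coding start sites 39.5% were bound (Wilson interval 32.4 to 47.1), above the 24.4% of other genes. This does not exclude neighbouring protein-coding promoters as the source, since reads from a copy near a promoter may be placed at an identical distant copy. The interval also treats genes as independent, while neighbouring tRNA genes can share a peak. Reads shared between identical copies stay open: 30.8% of the 52 tRNA genes of unique sequence were bound (19.9 to 44.3), and 23.3% of the 30 that were also over 2 kb away (11.8 to 40.9), intervals that hold the share of other genes. General recovery of RNA polymerase III genes stays open too, as 4 of 9 such genes of other kinds were bound (44.4%, Wilson interval 18.9 to 73.3, Fisher's exact p = 0.238).

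The 1311 peaks listed in replicate 3 alone lay at promoters in 74.4% of cases (Wilson interval 72.02 to 76.7), against at most 16.3% in random placements. This argues against calls spread evenly along the arms, while background that gathers at promoters was not tested. These peaks held a DRE in 3.13% of summit windows (Wilson interval 2.31 to 4.22), against 13.8% in the whole list of replicate 3. Of the 1311 peaks, 78.9% were present in the ranked lists of both other replicates, against at most 6.79% in placements. Most of these peaks were thus ranked in both other replicates but absent from their thresholded lists. The ranked lists are long, with 40130 and 31426 peaks in replicates 1 and 2, and evenly spread placements do not test background at promoters. The corresponding shares for the peaks of replicates 1 and 2 alone were 82.6% and 82.8%. Replicate 3 has the longest list, so a high share is not particular to lists that ended earlier and does not decide for that explanation. Depth is unknown, so why the lists of replicates 1 and 2 were shorter stays open.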

How the results depend on the processing

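Of 73 alternatives over 8 results, 72 kept their side of the threshold, or a count within 1.5 times. The exception was the number of enriched 6-mers, which was 363 in the report and 221 with windows of 51 bp, a shorter sequence in which fewer windows hold any given 6-mer; 209 of those 221 were among the 363, and the 10 named 6-mers were enriched under all 11 alternatives. The share of regions in all replicates ranged from 36.4% to 61.3%, the promoter share from 84.2% to 94.7%, the X to autosome ratio, which passed in no alternative, from 0.915 to 1.03 on either side of the 0.928 of start sites, the promoter to distal signal ratio from 1.25 to 1.42 and the percentile difference of shared peaks from 46.6 to 54.4. The number of gene lists past the threshold was 14, with 10 to 14 under alternatives, none in the opposite direction, and that of enriched consensus sequences was 9, with 7 to 11. Ribosomal, proteasome, insulator, histone, receptor, cuticle, snoRNA and microRNA calls passed in all 11 alternatives, tRNA and translation factor genes in 10, Polycomb and trithorax genes in 7, segment polarity genes in 5 and ecdysone genes in 3. Leaving out peaks that overlap a stronger peak and shifting calls along the gene order were chosen after seeing the data. Depth is unknown, so a gene without a peak may hold binding below the threshold of 830. Of the peaks listed in replicate 3 alone, 78.9% were in the ranked lists of both other replicates. Whether those peaks are true binding was not tested.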

Other observations

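The test of CGATA cores and the counts by signal decile were chosen only after the DRE result was seen.

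The DRE was more frequent in stronger peaks. It was 1.59% in the weakest signal decile of the conservative list (7 of 440 windows, Wilson interval 0.773 to 3.25), 8.20% in decile 5 and 31.0% in the strongest (136 of 439, 26.8 to 35.4). Of the 20 peaks named in the report 4 held a full DRE, at Creld, Pym, Nrg and hts, the window at Nrg holding 2. Distal peaks held a DRE in 5.05% of 614 windows and CGATA in 21.2%.

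Most of the 6-mers named in the report hold CGATA on either strand, so a hypothesis is that stronger peaks hold more CGATA cores whether or not they hold a complete DRE. Among 3280 summit windows without a DRE, leaving out peaks that overlap a stronger one, the upper 50% by signal held 1.02 ± 1.17 cores (SD over windows, n = 1640) and the lower 0.279 ± 0.626 (n = 1640), a ratio of 3.66 (2-sided permutation p = 1e-05, the smallest possible). The median ratio of the 59 other 5-mers of the same composition was 1.10; 1 of them, ATCGA, had a higher ratio than CGATA, 3.76, and it too is part of the DRE. At least 2 cores were present in 32.5% of the upper and 5.98% of the lower windows. Promoter and distal peaks were not separated in this test. Among all conservative peaks, CGATA was present in 48.9% of those near protein-coding but no tRNA start sites and in 21.2% of distal ones. Partial DRE sequence, CGATA or ATCGA, may go with stronger recovery of CG34224-eGFP; the pattern was found and tested on the same peaks, and which of the overlapping words matters was not tested.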
